A study of Mus musculus with 27 samples.

How the data were processed

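RNA from full-thickness mouse colon was extracted with Trizol and RNeasy, labelled with biotin and hybridized to an Affymetrix mouse array, 1 array per sample. The design text names a rat array, but the probe sets are those of a mouse array. The deposited values are log2 expression, 1 per probe set and array, normalized across all 27 arrays by the authors with affyPLM. The version, background step and summary method are not given in the sources used here, and the values were used as deposited. They lay between 2.10 and 14.25, and no count-like depth exists for arrays. Samples were grouped by the labels into 9 groups of 3 arrays.

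Of 45101 probe sets, 64 control probe sets were left out. The 34945 probe sets with 1 gene symbol gave 18193 genes, each represented by the probe set with the highest mean over all arrays, since 9010 genes had more than 1. The 932 probe sets with several symbols and the 9160 with none were left out of the gene tests and examined separately. Chromosomes were taken from assembly GRCm38.p6. Coordinates are not printed, since the array's own build is not given.

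limma (3.58.1, R 4.3.3) fitted 9 group means to each gene over all 27 arrays with 18 residual degrees of freedom. Contrasts were tested with the empirical Bayes moderated test (eBayes), two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast. The 17 contrasts were the 3 pairs of kinds of mice at each age and averaged over ages, 12 against 7 weeks in each kind, and the change from 7 to 12 weeks of the differences of conventional knockouts from wild types and from SPF knockouts. The change of the latter from 9 to 12 weeks was added after the data were seen. Fixed in advance were 38 lists, 19 of pathways and 19 of cell type markers, with 669 of 724 members measured. Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a contrast. Members were also counted at p-values adjusted within the list. Of 252 camera calls, 1 held with an estimated correlation (type I interferon, SPF knockouts against wild types, 7 weeks).

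Genes were named by a rule. In each comparison of groups it took the 6 largest rises and the 6 largest falls among called genes with all 3 arrays of 1 group beyond all 3 of the other (for averages, at least 8 of 9 arrays beyond the other group's median). It added up to 4 called members with the smallest adjusted p per list, and Il10 in every comparison. The text prints part of these, and names as such the genes chosen after their values were seen. For changes with age, genes named in the group comparisons were used again.

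The contrasts, lists, naming rule and most alternatives were chosen before the data were examined. Alternatives were a replicate block (replicate number within age), quantile normalization again, centring each array on its median, leaving out the 40% of genes with the lowest mean, all non-control probe sets, the mean of a gene's probe sets, an intensity trend in eBayes, array weights, only the arrays of the groups compared, a minimum absolute log2 difference of 1, and leaving out each array in turn. Added after the data were seen was a covariate, the clock score (mean of the clock genes higher at 7 weeks in conventional knockouts against wild types minus the mean of those lower). Splits of the arrays into groups of the same sizes were counted, at most 100 drawn.

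Tested on simulated data were the group means, replicate block, camera at the preset correlation, exchanged labels, genes apart and splits. For conventional knockouts against wild types at 9 weeks, 91% of 100 genes changed by 1 log2 unit were called. Of 100 changed by 2, 99% were called, as were 13 unchanged genes. Unequal spreads in real groups may change these rates. Permutation tests used 100000 draws. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.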

Results

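Gene expression was measured in full-thickness colon of mice on 27 arrays, 1 per sample. The samples fall into 9 groups of 3, from 3 kinds of mice at 7, 9 and 12 weeks of age. The kinds are Il10 knockouts in conventional housing, Il10 knockouts in specific pathogen free (SPF) housing, and wild types in conventional housing. Il10 encodes a cytokine that restrains inflammation, and mice that lack it can develop colitis when gut microbes are present. The label of the conventional knockouts is a short code, read by elimination, since the other codes name the SPF knockouts and the wild types. The 3 replicates of a group were picked by the authors by colon length and colonic damage, so they are not a random sample of the colony. The samples used here include no SPF wild types, so a comparison of SPF knockouts with wild types changes genotype and housing together. Array medians lay between 4.92 and 4.99 on the log2 scale, and Spearman correlations between arrays lay between 0.953 and 0.993. The number of arrays limits the precision. The p-values rest on the spread between samples within a group, shared over all 9 groups. The labels do not say whether a sample pooled animals, so this is not known to be a spread between animals. Xist was at most 4.52 and the Y-linked Eif2s3y at least 7.98 in all arrays. Wild-type 12-week replicate 2 stood apart in its actin signal, 0.95 higher at the 3' than at the 5' end on the log2 scale, and in the bioB spike-in (9.26, others at most 8.79), but not in Gapdh (0.002).

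Il10 itself was read by a single probe set, whose value was at least 4.66 in the 18 knockout arrays and at most 3.84 in the 9 wild-type arrays. The knockout allele and the position of the probe are not given, so this signal checks nothing about the knockout. Differences below are log2 differences of group means ± SE (n = 3 arrays per group) from 1 limma model of all arrays. Lists of genes fixed in advance were tested with camera against all other genes, with counts of measured members called, and medians of log2 differences.

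Conventional knockouts were first compared with wild types at 7 weeks, the youngest age. Here the 4 called genes with the largest differences, Dbp, Nr1d1, Nr1d2 and Nfil3, belonged to the circadian clock. The clock output factors Dbp (-5.04 ± 0.67, adjusted p = 0.000201), Nr1d1 (-3.15 ± 0.41), Nr1d2 (-2.82 ± 0.37), Tef (-2.25 ± 0.34) and Ciart (-2.04 ± 0.26) were lower in the knockouts. Nfil3, a repressor of Dbp targets, was higher (2.50 ± 0.24, adjusted p = 5.76e-06), as were the core clock genes Arntl (2.17 ± 0.33) and Cry1 (1.92 ± 0.24). Lonrf3 (1.85 ± 0.24) and the growth factor gene Hbegf (1.94 ± 0.29) also rose. A smaller set of immune and early response genes rose: the interferon-inducible GTPases Iigp1 (2.35 ± 0.48, adjusted p = 0.0242) and Irgm2 (1.25 ± 0.26), the transcription factors Fos (1.10 ± 0.20) and Atf3 (1.37 ± 0.31), and the endotoxin receptor gene Cd14 (0.96 ± 0.21). Apoc1 was lower (-2.14 ± 0.44), with wild types at 5.62 (SD 1.70) but 3.71 at 9 weeks. Il10 itself missed the threshold at 1.25 ± 0.29, adjusted p = 0.0507.

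Among the lists at 7 weeks, 4 of 17 genes rose and 7 fell (4 higher and 9 lower adjusted within the list, median -0.36, camera adjusted p = 0.000658, or 0.426 with an estimated correlation) for clock output genes. For the interferon gamma and Th1 list, 2 of 29 genes rose (11 higher adjusted within the list, median 0.39, camera adjusted p = 1.68e-08, or 0.434 with an estimated correlation). For the cell cycle, 0 of 24 genes passed limma's test (18 higher at an unadjusted p under 0.05, 17 higher adjusted within the list, median 0.57, camera adjusted p = 6.16e-14, or 0.426 with an estimated correlation). For the unfolded protein response, 1 of 20 genes rose (10 higher adjusted within the list, median 0.34, camera adjusted p = 4.77e-07, or 0.426 with an estimated correlation). For B cell markers, 0 of 13 genes passed limma's test (3 lower at an unadjusted p under 0.05, 2 lower adjusted within the list, median -0.49, camera adjusted p = 0.000161, or 0.637 with an estimated correlation). For pancreatic acinar markers, which can mark pancreas attached to the colon, 0 of 10 genes passed limma's test (6 lower at an unadjusted p under 0.05, 1 lower adjusted within the list, median -0.91, camera adjusted p = 2.6e-05, or 0.426 with an estimated correlation). This rested on wild-type 7-week replicate 1, with a list mean of 7.66 against 5.40 and 5.09 in replicates 2 and 3: without it the median was -0.144 and the camera call was lost.

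In all 92 genes were called (62 higher, 30 lower), 43 of them changed at least 2-fold, and in 91 of the 92 all 3 arrays of 1 group lay beyond all 3 of the other, which held for 18.6% of all genes (10% by chance). The count was 41, 60 and 37 without conventional knockout replicate 1, 2 or 3 at 7 weeks, 30 without wild-type 7-week replicate 2 and 156 without SPF knockout 12-week replicate 2, and Apoc1, Atf3, Cd14, Fos, Iigp1 and Irgm2 lost their calls in at least 1 of the leave-outs. With a score of the clock genes as a covariate, a setting chosen after the data were seen, limma called 0 genes (1167 at an unadjusted p under 0.05), and the cell cycle, unfolded protein and clock lists turned (medians -0.18, -0.074 and 0.065).

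At 9 weeks the conventional knockouts differed from wild types in 4375 genes (2582 higher, 1793 lower), 868 of them by at least 2-fold. S100a8 and S100a9, the subunits of the neutrophil protein calprotectin, were higher by 6.98 ± 1.12, adjusted p = 0.000249 and 6.65 ± 1.18. The chemokines Cxcl5, which draws neutrophils, and Cxcl9, which is induced by interferon gamma, rose by 5.93 ± 0.87 and 5.83 ± 0.69. The chloride channel regulator Clca4b (6.80 ± 0.83) and the acute phase gene Lrg1 (5.40 ± 0.66) rose as well. The largest falls were in the mucosal pentraxin Mptx1 (-7.07 ± 1.38, adjusted p = 0.00117), the transglutaminase Tgm3 (-4.95 ± 0.94), syncollin Sycn (-4.76 ± 0.83), the antimicrobial ribonuclease Ang4 (-3.85 ± 0.88) and the cytochrome P450 genes Cyp2c68 (-3.76 ± 0.69) and Cyp2f2 (-3.60 ± 0.66). Il10 was higher by 2.48 ± 0.29, adjusted p = 9.83e-06.

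**Figure D1:**
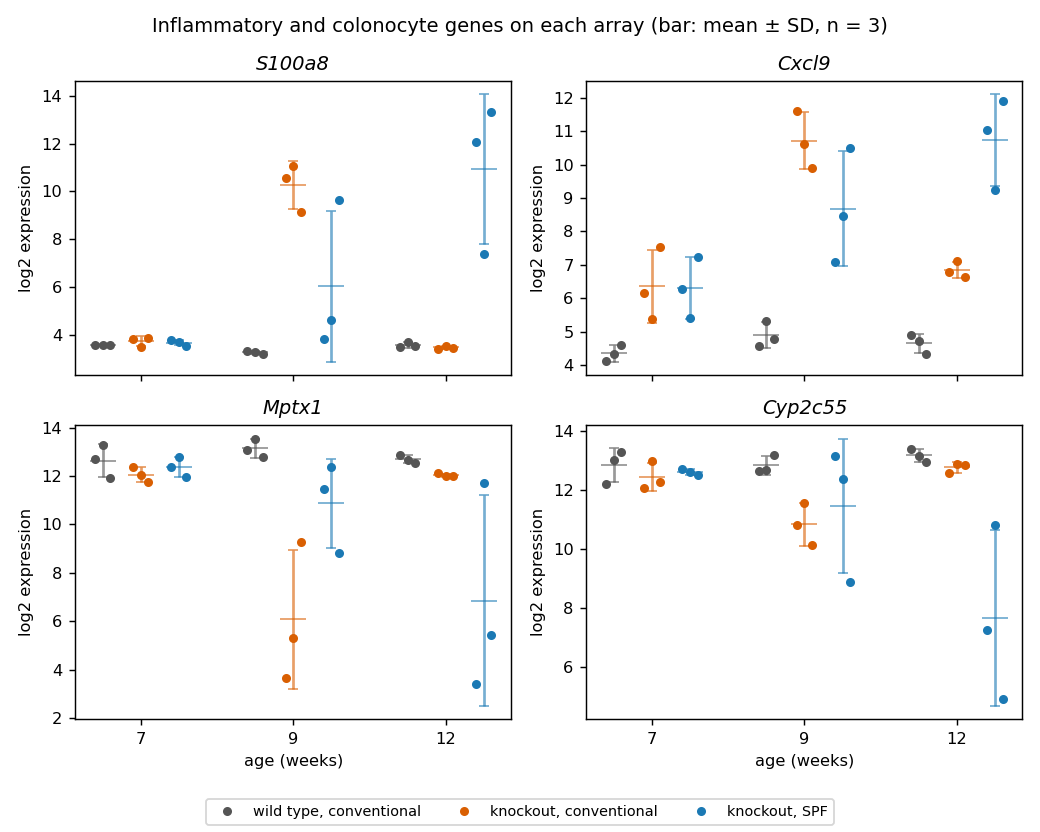
Log2 expression of S100a8, Cxcl9, Mptx1 and Cyp2c55 in each array (points) by age in weeks, with mean ± SD per group of 3 arrays. S100a8 averaged 10.26 in conventional knockouts at 9 weeks and 3.49 at 12 weeks, while SPF knockouts averaged 6.04 and 10.94 and wild types averaged between 3.27 and 3.60.

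At 9 weeks camera at the preset correlation called a number of immune lists, the unfolded protein response and the cell cycle higher, none of them with an estimated correlation. In the interferon gamma and Th1 list, 24 of 29 genes rose and 1 fell (24 higher and 1 lower adjusted within the list, median 2.14, camera adjusted p = 7.6e-20, or 0.189 with an estimated correlation). Examples were the immunoproteasome subunit Psmb9 (3.01 ± 0.25), the GTPase Iigp1 (5.32 ± 0.48) and the peptide transporter Tap1 (3.14 ± 0.29). In the type I interferon list, 14 of 21 genes rose (15 higher adjusted within the list, median 0.93, camera adjusted p = 1.01e-09, or 0.24 with an estimated correlation). Examples were the nucleic acid sensor Zbp1 (2.80 ± 0.22) and Ifit2 (2.90 ± 0.37). In the cytokine and chemokine list, 11 of 27 genes rose (14 higher adjusted within the list, median 0.82, camera adjusted p = 1.65e-07, or 0.351 with an estimated correlation). Examples were the chemokines Ccl8 (3.37 ± 0.39) and Ccl5 (2.65 ± 0.37). In the list of epithelial antimicrobial and acute phase genes, 14 of 21 genes rose and 3 fell (14 higher and 5 lower adjusted within the list, median 1.53, camera adjusted p = 0.000464, or 0.189 with an estimated correlation). The bactericidal lectin Reg3g (4.75 ± 0.66), the phospholipase Pla2g2a (3.28 ± 0.35) and the nitric oxide synthase Nos2 (2.73 ± 0.45) rose. In the MHC class II list, 5 of 10 genes rose (5 higher adjusted within the list, median 1.36, camera adjusted p = 0.000108, or 0.309 with an estimated correlation). The invariant chain Cd74 was at 2.71 ± 0.37 and H2-Ab1 at 2.49 ± 0.32. In the list of STAT3 targets and suppressors, 11 of 15 genes rose (11 higher adjusted within the list, median 1.08, camera adjusted p = 1.14e-06, or 0.201 with an estimated correlation). The cytokine signalling suppressor Socs3 was at 3.44 ± 0.45. In the matrix and remodelling list, 12 of 30 genes rose and 2 fell (13 higher and 2 lower adjusted within the list, median 0.39, camera adjusted p = 0.000452, or 0.351 with an estimated correlation). Examples were the proteinases Mmp10 (3.75 ± 0.59) and Mmp7 (3.43 ± 0.55). In the unfolded protein response, 9 of 20 genes rose and 1 fell (12 higher and 1 lower adjusted within the list, median 0.42, camera adjusted p = 0.00872, or 0.351 with an estimated correlation). In the cell cycle list, 23 of 24 genes rose (23 higher adjusted within the list, median 1.09, camera adjusted p = 9.84e-15, or 0.201 with an estimated correlation). Examples were the topoisomerase Top2a (1.23 ± 0.21) and Rrm2, which makes deoxynucleotides (2.13 ± 0.36).

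Some marker lists of immune and vessel cells were called higher at 9 weeks in the same way. For macrophages and monocytes, 20 of 22 genes rose (20 higher adjusted within the list, median 1.57, camera adjusted p = 5.2e-14, or 0.201 with an estimated correlation). The complement gene C1qa was at 1.62 ± 0.23 and the Fc receptor Fcgr3 at 2.18 ± 0.34. For T cells, 8 of 18 genes rose (9 higher adjusted within the list, median 0.46, camera adjusted p = 0.000272, or 0.351 with an estimated correlation). Cd3g was at 2.49 ± 0.33. For cytotoxic lymphocytes, 6 of 12 genes rose (6 higher and 1 lower adjusted within the list, median 0.34, camera adjusted p = 0.000272, or 0.201 with an estimated correlation). The granzyme Gzmb was at 3.45 ± 0.31 and Gzma at 3.60 ± 0.38. For neutrophils, 7 of 16 genes rose (7 higher and 1 lower adjusted within the list, median 0.69, camera adjusted p = 0.000452, or 0.351 with an estimated correlation). For dendritic cells, 4 of 11 genes rose (6 higher adjusted within the list, median 0.36, camera adjusted p = 0.012, or 0.335 with an estimated correlation). For endothelium, 5 of 15 genes rose (5 higher adjusted within the list, median 0.26, camera adjusted p = 0.00486, or 0.351 with an estimated correlation). Examples were the adhesion molecules Madcam1 (1.20 ± 0.20) and Icam1 (2.37 ± 0.49).

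Some epithelial lists and the muscle and nerve lists were called lower at 9 weeks, also at the preset correlation only. For colonocyte transport, 1 of 24 genes rose and 9 fell (2 higher and 12 lower adjusted within the list, median -0.78, camera adjusted p = 0.000862, or 0.351 with an estimated correlation). Examples were the chloride exchanger Slc26a3 (-1.36 ± 0.29) and Slc37a2 (-3.48 ± 0.77). For xenobiotic metabolism, 10 of 34 genes fell (12 lower adjusted within the list, median -0.61, camera adjusted p = 8.86e-06, or 0.351 with an estimated correlation). An example was Cyp4b1 (-3.08 ± 0.50). For goblet cells, 2 of 15 genes fell (2 lower adjusted within the list, median -0.30, camera adjusted p = 0.0082, or 0.552 with an estimated correlation). The mucus protein Clca1 was at -1.75 ± 0.43. For enteroendocrine and tuft cells, 7 of 14 genes fell (8 lower adjusted within the list, median -0.75, camera adjusted p = 0.00439, or 0.351 with an estimated correlation). The peptide hormone gene Insl5 was at -2.93 ± 0.68. For smooth muscle, 11 of 16 genes fell (15 lower adjusted within the list, median -0.60, camera adjusted p = 1.41e-06, or 0.351 with an estimated correlation). The filament protein Synm was at -1.02 ± 0.22. For enteric neurons, glia and interstitial cells, 8 of 16 genes fell (8 lower adjusted within the list, median -0.61, camera adjusted p = 1.64e-05, or 0.217 with an estimated correlation). Examples were the synaptic protein Snap25 (-1.36 ± 0.27) and Ano1, a channel of pacemaker cells (-1.56 ± 0.35).

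Other lists were not called by camera at 9 weeks, with adjusted p values from 0.117 for the clock to 0.992 for Th17 genes. Their called genes were 1 higher of 11, 1 higher adjusted within the list, for Th17 and IL-22, 2 higher of 14, 2 higher adjusted within the list, for Th2 genes, and 1 higher and 3 lower of 17, 1 higher and 3 lower adjusted within the list, for the clock. The medians of the Th2, junction, adipocyte and skeletal muscle lists (-0.03, 0.06, 0.02 and 0.003) and camera's direction differed in sign. Metabolic lists gave 2 higher and 3 lower of 23, 2 higher and 3 lower adjusted within the list, for fatty acid oxidation and 1 higher and 2 lower of 25, 2 lower adjusted within the list, for oxidative phosphorylation. Epithelial lists gave 2 higher and 4 lower of 21, 2 higher and 5 lower adjusted within the list, for junctions, with Ocln at -1.08 ± 0.16 and Cldn8 at -1.81 ± 0.36, and 3 higher and 4 lower of 16, 3 higher and 5 lower adjusted within the list, for crypt stem cells. Genes near Il10 on chromosome 1 gave 11 higher and 5 lower of 46, 14 higher and 7 lower adjusted within the list. Lymphocyte lists gave 3 higher and 1 lower of 9, 3 higher and 1 lower adjusted within the list, for regulatory T cells, with the checkpoint receptor Ctla4 at 1.43 ± 0.26, then 1 lower of 13, 0 adjusted within the list, for B cells and 1 higher of 12, 1 higher adjusted within the list, for plasma cells. The remaining markers gave 2 higher of 13, 2 higher adjusted within the list, for eosinophils and mast cells, 1 lower of 8, 1 lower adjusted within the list, for adipocytes, 2 lower of 10, 2 lower adjusted within the list, for pancreas, with the colipase Clps at -3.33 ± 0.47, and 1 lower of 13, 0 adjusted within the list, for skeletal muscle. With limma, 0 of 4 erythroid and 0 of 4 sex-linked genes passed (0 of 4, 0 unadjusted and 0 of 4, 2 lower unadjusted).

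In 96.9% of the genes called at 9 weeks, and in each gene named, all 3 knockout arrays lay beyond all 3 wild-type arrays, which held for 42.5% of all genes. Without conventional knockout 9-week replicate 1 the count was 2119.

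At 12 weeks 82 genes differed between conventional knockouts and wild types (48 higher, 34 lower), 25 of them by at least 2-fold. The antimicrobial lectin Reg3g (3.22 ± 0.66, adjusted p = 0.0365), the GTPase Iigp1 (2.48 ± 0.48) and antigen presentation genes rose, the latter including Cd74 (2.21 ± 0.37), H2-DMa (1.58 ± 0.32), H2-Ab1 (1.56 ± 0.32), H2-Aa (1.36 ± 0.28), Tap1 (1.61 ± 0.29), Psmb8 (1.39 ± 0.27) and Psmb9 (1.22 ± 0.25). Zbp1 rose by 1.34 ± 0.22, Cebpd by 0.83 ± 0.18 and the junction gene Tjp3 by 0.45 ± 0.10. Col1a1 was higher (1.23 ± 0.25), wild types having fallen with age to 7.67. The genes with the smallest adjusted p were Mid1, an X-linked ubiquitin ligase gene (-2.54 ± 0.28, adjusted p = 6.57e-05), the mitochondrial dehydrogenase gene D2hgdh (-1.05 ± 0.12, adjusted p = 6.57e-05), Wdfy1 (2.26 ± 0.26, adjusted p = 7.6e-05) and the kinase gene Stk25 (-1.38 ± 0.16, adjusted p = 9.91e-05). Gal3st2 (-1.49 ± 0.32), Ccdc39 (-1.11 ± 0.20) and Micu3 (-1.10 ± 0.24) fell. Il10 missed the threshold at 1.26 ± 0.29, adjusted p = 0.0510.

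Among the 12-week lists, 6 of 29 genes rose (13 higher adjusted within the list, median 0.65, camera adjusted p = 1.09e-08, or 0.439 with an estimated correlation), for interferon gamma and Th1 genes. For type I interferon, 1 of 21 genes rose (6 higher adjusted within the list, median 0.54, camera adjusted p = 6.02e-08, or 0.439 with an estimated correlation). For MHC class II, 4 of 10 genes rose (5 higher adjusted within the list, median 0.65, camera adjusted p = 0.00045, or 0.439 with an estimated correlation). For the clock, 0 of 17 genes passed limma's test (2 higher and 9 lower at an unadjusted p under 0.05, 2 higher and 9 lower adjusted within the list, median -0.47, camera adjusted p = 0.00406, or 0.439 with an estimated correlation).

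All 82 genes called at 12 weeks had all 3 arrays of 1 group beyond all 3 of the other, and of the 20 called genes named here only Wdfy1, Mid1, Stk25 and D2hgdh kept their calls in every leave-out. The count was 834 without wild-type 12-week replicate 1, 11 without replicate 2, the array with the high actin ratio, 12, 13 and 14 without conventional knockout 12-week replicate 1, 2 or 3, and 8 with the clock score as a covariate. It fell to between 39 and 50 without conventional knockout 7-week replicate 2 (39) or 9-week replicate 1 (45) or 2 (45), SPF knockout 7-week replicate 1 (40), 2 (39) or 3 (39) or 9-week replicate 1 (48) or 2 (40), or wild-type 7-week replicate 2 (50) or 9-week replicate 1 (41), 2 (46) or 3 (45).

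Averaged over the ages, 3344 genes differed between conventional knockouts and wild types (2067 higher, 1277 lower). Iigp1 (3.38 ± 0.28, adjusted p = 7.32e-08), Cxcl9 (3.35 ± 0.40), Reg3g (3.33 ± 0.38), Clca4b (4.11 ± 0.48), Lrg1 (2.40 ± 0.38), Gzmb (1.56 ± 0.18) and the tryptophan-degrading enzyme gene Ido1 (3.03 ± 0.32) rose, as did Il10 (1.66 ± 0.17). Mid1 (-2.12 ± 0.16, adjusted p = 2.57e-08), Dbp (-2.77 ± 0.39), Mptx1 (-2.77 ± 0.80), Ang4 (-2.35 ± 0.51), Cyp4b1 (-2.16 ± 0.29) and Sycn (-1.85 ± 0.48) fell. For interferon gamma and Th1 genes, 22 of 29 genes rose (22 higher and 1 lower adjusted within the list, median 1.11, camera adjusted p = 6.6e-20, or 0.136 with an estimated correlation). For B cells, 4 of 13 genes fell (4 lower adjusted within the list, median -0.42, camera adjusted p = 0.00228, or 0.55 with an estimated correlation). Examples were Ms4a1, which encodes the surface protein CD20 (-1 ± 0.33) and the IgM receptor gene Fcmr, also in the list of genes near Il10 (-1.005 ± 0.24). The Ms4a1 call was lost in each of 11 leave-outs and the Mptx1 call without conventional knockout 9-week replicate 1. With the clock score as a covariate the count was 15.

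**Figure D2:**
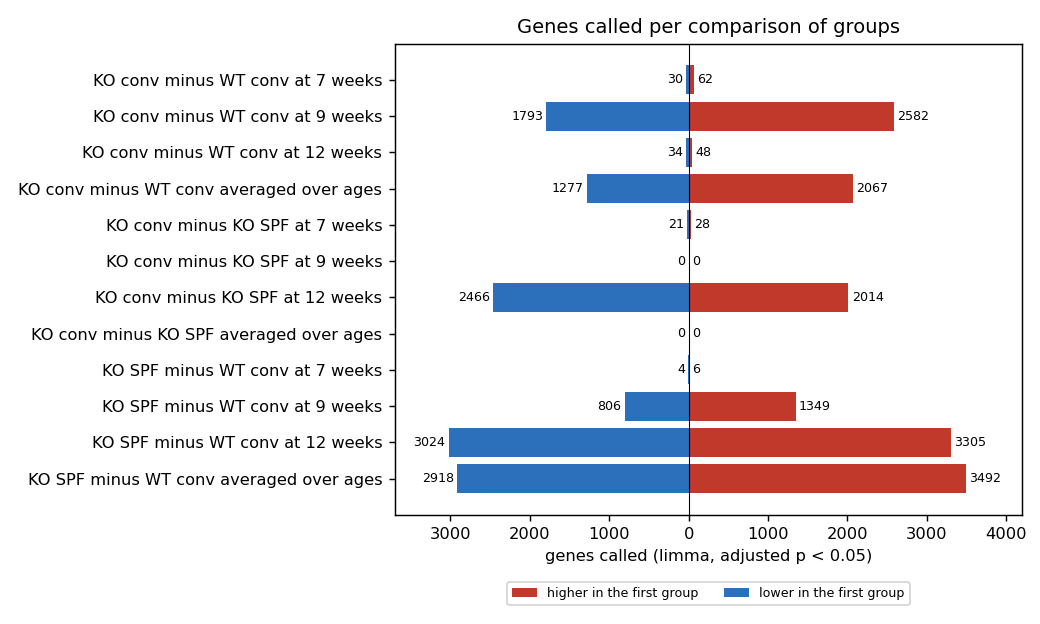
Number of genes called higher and lower in each comparison of groups at 7, 9 and 12 weeks (bars, genes at an adjusted p under the threshold). The SPF knockouts differed from wild types in 10, 2155 and 6329 genes and the conventional knockouts in 92, 4375 and 82 genes.

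SPF knockouts at 7 weeks differed from wild types in 10 genes, all named here. Wdfy1 (2.26 ± 0.26, adjusted p = 0.000123), the interferon-inducible sensor Zbp1 (1.31 ± 0.22, adjusted p = 0.0128), the peptide-amidating enzyme gene Pam (1.17 ± 0.20), 3110009E18Rik (1.16 ± 0.15), Panct2 (1.02 ± 0.15) and Rab3gap1 (0.52 ± 0.07) were higher. Mid1 (-1.90 ± 0.28, adjusted p = 0.00268), Stk25 (-1.22 ± 0.16), Hpx (-1.11 ± 0.20, wild types at 4.33 but 3.59 at 9 weeks) and D2hgdh (-1.01 ± 0.12) were lower. In the type I interferon list, 1 of 21 genes rose (19 higher adjusted within the list, median 0.84, camera adjusted p = 2.79e-30, or 0.0481 with an estimated correlation), the only list called with both. In the interferon gamma and Th1 list, 0 of 29 genes passed limma's test (14 higher at an unadjusted p under 0.05, 12 higher adjusted within the list, median 0.38, camera adjusted p = 7.09e-14, or 0.27 with an estimated correlation). Il10 did not pass (1.06 ± 0.29, adjusted p = 0.327). The 10 genes had no overlap of arrays, and the count was 38 without wild-type 7-week replicate 3. Hpx lost its call in 11 leave-outs, Pam without SPF knockout 7-week replicate 1 or 2 or wild-type 7-week replicate 2, and Zbp1 without any of these or SPF knockout replicate 3.

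At 9 weeks 2155 genes differed between SPF knockouts and wild types (1349 higher, 806 lower). Clca4b (5.64 ± 0.83, adjusted p = 0.000381), Reg3g (4.79 ± 0.66), Iigp1 (4.32 ± 0.48, adjusted p = 4.18e-05), Lrg1 (4.27 ± 0.66), Ido1 (4.15 ± 0.56) and Cxcl9 (3.79 ± 0.69) rose most. Clps (-2.46 ± 0.47, adjusted p = 0.00324), Mid1 (-2.43 ± 0.28), Dbp (-2.18 ± 0.67) and the cytochrome P450 genes Cyp2d12 (-2.27 ± 0.69), Cyp2f2 (-2.17 ± 0.66) and Cyp4b1 (-2.16 ± 0.50) fell most among called genes with no overlap between the arrays of the 2 groups. Il10 was higher by 2.03 ± 0.29.

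By list at 9 weeks, 17 of 29 genes rose (19 higher adjusted within the list, median 1.56, camera adjusted p = 5.52e-15, or 0.296 with an estimated correlation), for interferon gamma and Th1 genes such as Psmb9 (2.18 ± 0.25) and Ifi47 (2.90 ± 0.35). For type I interferon, 11 of 21 genes rose (13 higher adjusted within the list, median 0.69, camera adjusted p = 5.39e-10, or 0.31 with an estimated correlation). Examples were Zbp1 (2.05 ± 0.22) and Oasl2 (1.87 ± 0.35). For the cell cycle, 22 of 24 genes rose (23 higher adjusted within the list, median 1.02, camera adjusted p = 1.92e-17, or 0.296 with an estimated correlation). Examples were cyclin Ccna2 (1.13 ± 0.17) and the mitotic kinase Aurka (1.53 ± 0.28). For antimicrobial genes, 10 of 21 genes rose and 1 fell (10 higher and 2 lower adjusted within the list, median 1.17, camera adjusted p = 0.00117, or 0.296 with an estimated correlation). Examples were Pla2g2a (2.68 ± 0.35) and the oxidase partner Duoxa2 (1.58 ± 0.34). For STAT3 targets, 7 of 15 genes rose (8 higher adjusted within the list, median 0.59, camera adjusted p = 6.9e-05, or 0.31 with an estimated correlation). An example was Socs3 (3.00 ± 0.45). For MHC class II, 5 of 10 genes rose and 1 fell (5 higher and 1 lower adjusted within the list, median 0.61, camera adjusted p = 0.0204, or 0.733 with an estimated correlation), a call lost without SPF knockout 9-week replicate 2 or 3. Examples were Cd74 (1.87 ± 0.37) and H2-DMa (1.90 ± 0.32). The chemokines Ccl8 (1.69 ± 0.39) and Cxcl5 (3.12 ± 0.87) rose. The granzymes Gzmb (2.13 ± 0.31) and Gzma (1.97 ± 0.38), the proteinase Mmp10 (1.98 ± 0.59), Cd14 (1.07 ± 0.21) and the chaperone Hspa5 (0.79 ± 0.18) rose. For smooth muscle, 4 of 16 genes fell (14 lower adjusted within the list, median -0.64, camera adjusted p = 1.23e-07, or 0.433 with an estimated correlation). Examples were Cald1 (-0.71 ± 0.15) and Synm (-0.90 ± 0.22). For enteric neurons, 3 of 16 genes fell (8 lower adjusted within the list, median -0.60, camera adjusted p = 6.9e-05, or 0.31 with an estimated correlation). Examples were Snap25 (-1.13 ± 0.27) and the neuropeptide gene Vip (-0.98 ± 0.28).

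Without SPF knockout 9-week replicate 3 the count was 283, and it was 1031, 901 and 1121 without wild-type 9-week replicate 1, 2 or 3. Without that SPF array Cald1, Ccl8, Cxcl5, Cyp2d12, Cyp2f2, Cyp4b1, Dbp, Duoxa2, Hspa5, Mmp10, Snap25, Synm and Vip lost their calls, and Cxcl5, Cyp2d12, Cyp2f2, Dbp, Mmp10 and Vip lost them without at least 1 wild-type 9-week array too. The count was 281 with the clock score as a covariate.

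At 12 weeks the SPF knockouts differed from wild types in 6329 genes (3305 higher, 3024 lower), 1446 of them by at least 2-fold. S100a8 (7.35 ± 1.12, adjusted p = 8.41e-05), S100a9 (6.97 ± 1.18), Lrg1 (6.50 ± 0.66, adjusted p = 2.19e-06), Clca4b (6.46 ± 0.83), Cxcl5 (6.37 ± 0.87) and Cxcl9 (6.09 ± 0.69) rose most. Mptx1 (-5.86 ± 1.38, adjusted p = 0.00232), the cytochrome P450 genes Cyp2c55 (-5.51 ± 0.96) and Cyp4b1 (-4.24 ± 0.50), Dbp (-4.07 ± 0.67), the peroxisomal thiolase Acaa1b (-4.00 ± 0.56) and Ang4 (-3.96 ± 0.88) fell most. Il10 was higher by 2.77 ± 0.29.

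For interferon gamma and Th1 genes at 12 weeks, 25 of 29 genes rose (25 higher adjusted within the list, median 2.47, camera adjusted p = 2.03e-16, or 0.22 with an estimated correlation). Examples were Tap1 (3.46 ± 0.29) and Psmb9 (2.70 ± 0.25). For cytokines and chemokines, 22 of 27 genes rose (24 higher adjusted within the list, median 1.33, camera adjusted p = 6.89e-11, or 0.264 with an estimated correlation). Examples were Ccl8 (3.03 ± 0.39) and the IL-6 family member Il11 (2.24 ± 0.31). For STAT3 targets, 13 of 15 genes rose (13 higher adjusted within the list, median 1.41, camera adjusted p = 4.88e-09, or 0.16 with an estimated correlation). Examples were Socs3 (3.97 ± 0.45) and Cebpd (2.09 ± 0.18). For antimicrobial genes, 13 of 21 genes rose and 2 fell (13 higher and 3 lower adjusted within the list, median 1.66, camera adjusted p = 0.000547, or 0.16 with an estimated correlation). Examples were Pla2g2a (3.76 ± 0.35) and Nos2 (3.01 ± 0.45). For MHC class II, 5 of 10 genes rose (5 higher adjusted within the list, median 1.37, camera adjusted p = 7.83e-05, or 0.264 with an estimated correlation). Examples were Cd74 (3.36 ± 0.37) and H2-DMa (3.13 ± 0.32). For type I interferon, 14 of 21 genes rose (14 higher adjusted within the list, median 0.73, camera adjusted p = 7.83e-05, or 0.308 with an estimated correlation). An example was Zbp1 (2.56 ± 0.22). For matrix and remodelling, 17 of 30 genes rose and 2 fell (17 higher and 2 lower adjusted within the list, median 0.66, camera adjusted p = 0.000385, or 0.308 with an estimated correlation). Examples were the proteinases Mmp10 (4.41 ± 0.59) and Mmp13 (3.68 ± 0.55). For the cell cycle, 23 of 24 genes rose (23 higher adjusted within the list, median 1.05, camera adjusted p = 2.18e-11, or 0.264 with an estimated correlation). The growth regulator Myc rose (1.24 ± 0.20) and the stem cell receptor Lgr5 fell (-1.26 ± 0.20). The Th17 cytokine gene Il17a rose by 1.32 ± 0.35, with overlap between the arrays of the groups and with the call lost without SPF knockout 12-week replicate 1, and the Th17 factor Batf rose by 0.66 ± 0.15.

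For macrophages at 12 weeks, 18 of 22 genes rose (20 higher adjusted within the list, median 1.77, camera adjusted p = 5.52e-11, or 0.264 with an estimated correlation). Examples were Cd14 (1.97 ± 0.21) and C1qa (1.57 ± 0.23). For neutrophils, 12 of 16 genes rose (14 higher adjusted within the list, median 1.55, camera adjusted p = 6.16e-06, or 0.273 with an estimated correlation). For T cells, 9 of 18 genes rose (11 higher adjusted within the list, median 0.46, camera adjusted p = 0.000424, or 0.296 with an estimated correlation). Cd3g was at 1.61 ± 0.33. The granzyme Gzmb (2.89 ± 0.31) and the adhesion genes Icam1 (2.61 ± 0.49) and Madcam1 (0.87 ± 0.20) rose.

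Some lists of the epithelium, muscle and nerves were called lower at 12 weeks at the preset correlation. For xenobiotic metabolism, 25 of 34 genes fell (28 lower adjusted within the list, median -1.41, camera adjusted p = 2.41e-12, or 0.264 with an estimated correlation). Examples were the sulfotransferase Sult1c2 (-3.64 ± 0.50) and the esterase Ces1g (-3.37 ± 0.49). For colonocyte transport, 1 of 24 genes rose and 15 fell (1 higher and 15 lower adjusted within the list, median -1.16, camera adjusted p = 6.16e-06, or 0.264 with an estimated correlation). Examples were guanylin, Guca2a (-2.37 ± 0.45), and Slc26a3 (-1.49 ± 0.29). For fatty acid oxidation, 2 of 23 genes rose and 14 fell (2 higher and 16 lower adjusted within the list, median -0.68, camera adjusted p = 0.000148, or 0.294 with an estimated correlation). For goblet cells, 9 of 15 genes fell (11 lower adjusted within the list, median -0.65, camera adjusted p = 0.000126, or 0.308 with an estimated correlation). Examples were Clca1 (-2.27 ± 0.43) and the kallikrein Klk1 (-2.35 ± 0.50). For enteroendocrine and tuft cells, 1 of 14 genes rose and 10 fell (1 higher and 10 lower adjusted within the list, median -1.32, camera adjusted p = 0.000141, or 0.264 with an estimated correlation). Examples were Chgb (-2.40 ± 0.37) and the serotonin-making enzyme Tph1 (-2.72 ± 0.45). For smooth muscle, 16 of 16 genes fell (16 lower adjusted within the list, median -1.12, camera adjusted p = 2.13e-11, or 0.264 with an estimated correlation). Examples were the myosin Myh11 (-1.51 ± 0.24) and Synm (-1.59 ± 0.22). For enteric neurons, glia and interstitial cells, 1 of 16 genes rose and 11 fell (1 higher and 12 lower adjusted within the list, median -0.78, camera adjusted p = 0.000141, or 0.264 with an estimated correlation). Examples were Snap25 (-1.76 ± 0.27) and Kit, a receptor of pacemaker cells (-1.62 ± 0.38). For the clock, 1 of 17 genes rose and 7 fell (1 higher and 9 lower adjusted within the list, median -0.65, camera adjusted p = 0.00797, or 0.264 with an estimated correlation).

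In 78.0% of the genes called at 12 weeks all 3 SPF knockout arrays lay beyond all 3 wild-type arrays, and S100a8 lay at 12.06, 7.41 and 13.34 in SPF knockout replicates 1, 2 and 3. No single array moved the count by more than 1.5 times, while the clock score as a covariate gave 189 and the 6 arrays of these groups alone gave 1321.

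Averaged over the ages 6410 genes differed between SPF knockouts and wild types (3492 higher, 2918 lower). Zbp1 (1.98 ± 0.13, adjusted p = 3.66e-09), Iigp1 (3.82 ± 0.28, adjusted p = 8.24e-09), Clca4b (4.99 ± 0.48), Lrg1 (4.14 ± 0.38), Reg3g (4.11 ± 0.38), Cxcl9 (3.95 ± 0.40), Ido1 (3.80 ± 0.32) and Il10 (1.95 ± 0.17) were higher. Ang4 (-2.87 ± 0.51), Mptx1 (-2.79 ± 0.80), Cyp4b1 (-2.52 ± 0.29), Cyp2c55 (-2.38 ± 0.55), Sycn (-2.24 ± 0.48) and Clps (-2.08 ± 0.27) were lower. For smooth muscle, 16 of 16 genes fell (16 lower adjusted within the list, median -0.63, camera adjusted p = 3.24e-10, or 0.298 with an estimated correlation). Chosen after their values were seen, the antigen processing genes Tap1 (2.21 ± 0.17), Psmb8 (2.01 ± 0.16) and Nlrc5 (2.76 ± 0.22), the GTPase Igtp (2.58 ± 0.21), and Wdfy1 (1.77 ± 0.15), Stk25 (-1.34 ± 0.09) and Mid1 (-1.97 ± 0.16) had no overlap between all 18 knockout and all 9 wild-type arrays. With the clock score as a covariate 1107 genes were called.

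The comparison of conventional with SPF knockouts holds the genotype and changes the housing. At 7 weeks 49 genes differed (28 higher, 21 lower), and the clock genes led again. Dbp (-5.08 ± 0.67, adjusted p = 0.000327), Nr1d1 (-3.07 ± 0.41), Nr1d2 (-2.80 ± 0.37), Tef (-2.17 ± 0.34), Ciart (-2.09 ± 0.26) and Hlf (-2.08 ± 0.37) were lower in the conventional knockouts. Nfil3 (2.17 ± 0.24, adjusted p = 0.00015), Arntl (2.27 ± 0.33), its partner Npas2 (1.79 ± 0.26), Cry1 (1.83 ± 0.24), Lonrf3 (1.78 ± 0.24), Fos (1.09 ± 0.20) and the tight junction gene Cldn8 (1.69 ± 0.36) were higher. For the clock, 4 of 17 genes rose and 7 fell (5 higher and 8 lower adjusted within the list, median -0.26, camera adjusted p = 0.000308, or 0.263 with an estimated correlation). In the type I interferon list, 0 of 21 genes passed limma's test (15 lower at an unadjusted p under 0.05, 15 lower adjusted within the list, median -0.71, camera adjusted p = 6.47e-21, or 0.202 with an estimated correlation). Il10 was at 0.20 ± 0.29, adjusted p = 1.00. All 49 called genes had all 3 arrays of 1 group beyond the other. The count was 19, 23 and 25 without conventional knockout 7-week replicate 1, 2 or 3 and 31, 18 and 20 without SPF knockout 7-week replicate 1, 2 or 3, and Cldn8, Fos and Hlf lost their calls in some of these leave-outs. With the clock score as a covariate limma called 0 genes (1032 at an unadjusted p under 0.05), and the clock list turned (median 0.19).

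**Figure D3:**
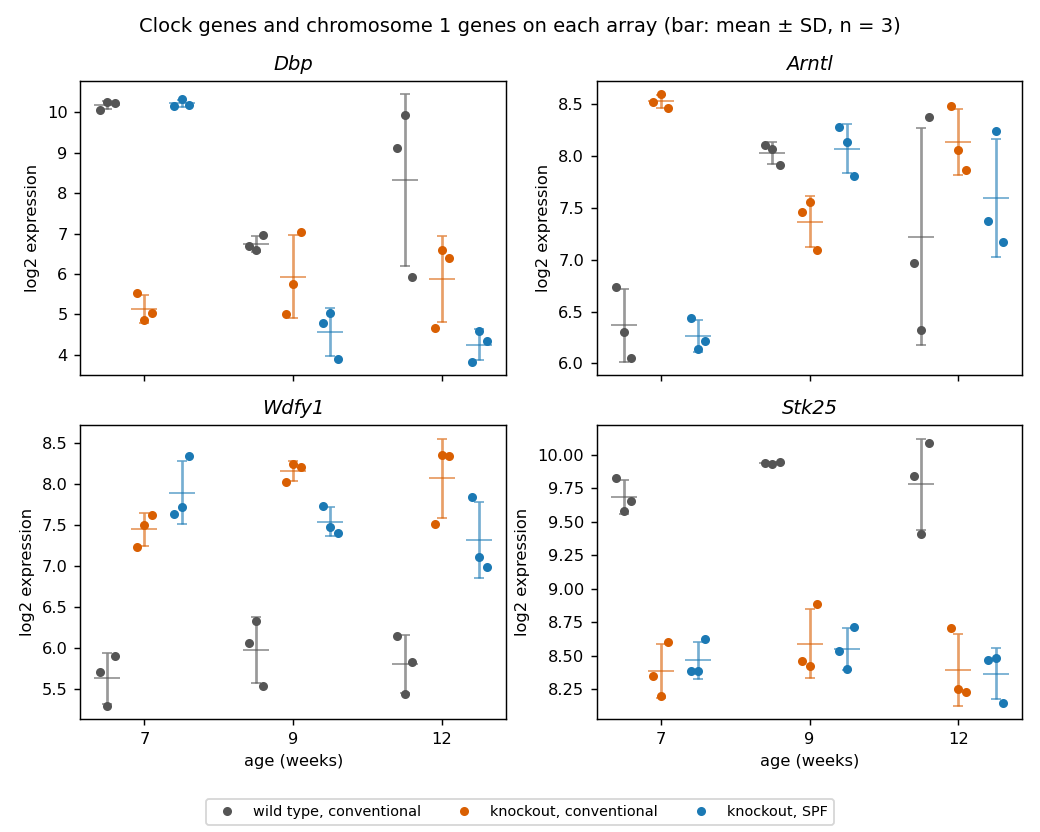
Log2 expression of the clock genes Dbp and Arntl and of the chromosome 1 genes Wdfy1 and Stk25 in each array (points) by age in weeks, with mean ± SD per group of 3 arrays. At 7 weeks Dbp averaged 5.14 in conventional knockouts, 10.22 in SPF knockouts and 10.18 in wild types.

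At 9 weeks limma called 0 genes between the knockouts (1468 at an unadjusted p under 0.05), and Il10 was at 0.45 ± 0.29, adjusted p = 0.767. Some immune lists were called higher in the conventional knockouts by camera at the preset correlation, while B cells (median -0.21) and Th2 genes were not called. For macrophages, 0 of 22 genes passed limma's test (17 higher at an unadjusted p under 0.05, 17 higher adjusted within the list, median 0.98, camera adjusted p = 1.19e-21, or 0.0837 with an estimated correlation). For interferon gamma and Th1 genes, 0 of 29 genes passed limma's test (20 higher and 1 lower at an unadjusted p under 0.05, 17 higher and 1 lower adjusted within the list, median 0.77, camera adjusted p = 1.59e-15, or 0.128 with an estimated correlation). For cytokines, 0 of 27 genes passed limma's test (11 higher at an unadjusted p under 0.05, 5 higher adjusted within the list, median 0.64, camera adjusted p = 1.44e-12, or 0.221 with an estimated correlation). For MHC class II, 0 of 10 genes passed limma's test (6 higher at an unadjusted p under 0.05, 5 higher adjusted within the list, median 0.76, camera adjusted p = 1e-06, or 0.128 with an estimated correlation). Colonocyte transport had a negative median, and 0 of 24 genes passed limma's test (5 lower at an unadjusted p under 0.05, 0 adjusted within the list, median -0.38, camera adjusted p = 7.55e-06, or 0.262 with an estimated correlation). Without 1 array the count was 18 (SPF knockout 9-week replicate 3), 185 and 23 (SPF knockout 12-week replicates 2 and 3), 2 (conventional knockout 9-week replicate 3) or 1 (SPF knockout 7-week replicate 3), and it was 3681 with array weights, which gave SPF knockout 9-week replicate 3 a weight of 0.344.

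At 12 weeks the order turned, and the arrays labelled SPF carried the higher inflammatory values. Conventional and SPF knockouts differed in 4480 genes (2014 higher and 2466 lower in conventional), 938 of them by at least 2-fold. S100a8 (-7.45 ± 1.12, adjusted p = 0.00109), S100a9 (-6.66 ± 1.18), Cxcl5 (-5.76 ± 0.87), Lrg1 (-5.33 ± 0.66, adjusted p = 0.000496), the keratinocyte envelope gene Sprr2h (-4.78 ± 0.86) and the siderophore-binding Lcn2 (-4.38 ± 0.82) were lower in conventional knockouts. Mptx1 (5.19 ± 1.38, adjusted p = 0.0096), Cyp2c55 (5.10 ± 0.96), the calcium-binding S100g (3.66 ± 0.81), the gasdermin Gsdmc2 (3.43 ± 0.67), the oxidase Hao2 (3.26 ± 0.65) and the sulfotransferase Sult1a1 (3.20 ± 0.72) were higher in them. Il10 was lower by -1.51 ± 0.29, adjusted p = 0.00227.

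In the interferon gamma and Th1 list, 23 of 29 genes fell (24 lower adjusted within the list, median -1.55, camera adjusted p = 5.46e-14, or 0.249 with an estimated correlation). Examples were Tap1 (-1.85 ± 0.29) and Ubd (-3.74 ± 0.63). In the cytokine list, 21 of 27 genes fell (23 lower adjusted within the list, median -1.59, camera adjusted p = 1.96e-13, or 0.249 with an estimated correlation). Examples were Il11 (-2.10 ± 0.31), Lif (-1.78 ± 0.29) and Ccl5 (-2.30 ± 0.37). For STAT3 targets, 10 of 15 genes fell (12 lower adjusted within the list, median -1.13, camera adjusted p = 1.29e-07, or 0.249 with an estimated correlation). An example was Socs3 (-2.69 ± 0.45). For antimicrobial genes, 3 of 21 genes rose and 9 fell (5 higher and 9 lower adjusted within the list, median -0.90, camera adjusted p = 0.00672, or 0.249 with an estimated correlation). Examples were Pla2g2a (-2.83 ± 0.35) and Nos2 (-2.76 ± 0.45). For MHC class II, 5 of 10 genes fell (5 lower adjusted within the list, median -0.83, camera adjusted p = 0.0023, or 0.348 with an estimated correlation). Cd74 was at -1.15 ± 0.37. For matrix and remodelling, 3 of 30 genes rose and 14 fell (3 higher and 14 lower adjusted within the list, median -0.26, camera adjusted p = 0.00937, or 0.492 with an estimated correlation), a call lost without conventional 12-week replicate 1 or SPF 12-week replicate 3. Examples were Mmp10 (-3.57 ± 0.59) and Mmp13 (-3.32 ± 0.55). For the cell cycle, 17 of 24 genes fell (20 lower adjusted within the list, median -0.77, camera adjusted p = 1.35e-10, or 0.249 with an estimated correlation). Rrm2 was at -2.19 ± 0.36. For neutrophils, 1 of 16 genes rose and 13 fell (1 higher and 14 lower adjusted within the list, median -1.46, camera adjusted p = 5.13e-07, or 0.249 with an estimated correlation). For macrophages, 17 of 22 genes fell (17 lower adjusted within the list, median -1.24, camera adjusted p = 3.24e-10, or 0.249 with an estimated correlation). Examples were Fcgr3 (-1.83 ± 0.34) and the chemokine receptor Ccr2 (-1.82 ± 0.34). Gzmb (-1.90 ± 0.31), the adhesion genes Vcam1 (-1.68 ± 0.34) and Icam1 (-2.43 ± 0.49) and Zbp1 (-1.23 ± 0.22) fell, as did Il17a (-1.26 ± 0.35) and the macrophage lectin Chil3 (-3.81 ± 0.88), whose arrays overlapped.

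Some epithelial lists and the muscle and nerve lists were called higher in the conventional knockouts at 12 weeks at the preset correlation. For xenobiotic metabolism, 24 of 34 genes rose (25 higher adjusted within the list, median 1.41, camera adjusted p = 1.98e-12, or 0.249 with an estimated correlation). Examples were Ces1g (2.81 ± 0.49) and Sult1c2 (2.76 ± 0.50). For colonocyte transport, 13 of 24 genes rose (15 higher adjusted within the list, median 1.19, camera adjusted p = 3.25e-07, or 0.249 with an estimated correlation). Examples were Guca2a (2.20 ± 0.45) and the carbonic anhydrase Car2 (1.24 ± 0.23). For fatty acid oxidation, 13 of 23 genes rose and 2 fell (14 higher and 3 lower adjusted within the list, median 0.66, camera adjusted p = 0.000123, or 0.346 with an estimated correlation). The fatty acid carrier Fabp2 was at 2.16 ± 0.46. For goblet cells, 12 of 15 genes rose (14 higher adjusted within the list, median 0.80, camera adjusted p = 2.97e-07, or 0.253 with an estimated correlation). Examples were Clca1 (2.33 ± 0.43) and Klk1 (2.44 ± 0.50). For enteroendocrine and tuft cells, 10 of 14 genes rose and 1 fell (11 higher and 1 lower adjusted within the list, median 1.29, camera adjusted p = 8.42e-06, or 0.249 with an estimated correlation). Examples were Chgb (2.00 ± 0.37) and Chga (1.95 ± 0.39), while Tac1, a neuropeptide gene of that list, fell (-1.92 ± 0.37). For smooth muscle, 15 of 16 genes rose (15 higher adjusted within the list, median 1.09, camera adjusted p = 8.87e-12, or 0.249 with an estimated correlation). Examples were Myh11 (1.39 ± 0.24) and smoothelin, Smtn (1.43 ± 0.26). For enteric neurons, 7 of 16 genes rose (9 higher adjusted within the list, median 0.41, camera adjusted p = 0.000294, or 0.249 with an estimated correlation). Examples were Snap25 (1.19 ± 0.27) and Kit (1.64 ± 0.38). The junction gene Ocln (0.84 ± 0.16) and Lgr5 (1.16 ± 0.20) rose.

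In 78.5% of the genes called, the 3 arrays of 1 group lay beyond the 3 of the other. The count was 2176 and 1357 without SPF 12-week replicate 1 or 3 and 2922 without conventional 12-week replicate 2. Of the genes named, Cd74 lost its call without SPF 12-week replicate 1 or 3 or any conventional 12-week array. Il17a and Mptx1 lost theirs without SPF replicate 1 or 3, and Kit without SPF replicate 3. With these 6 arrays alone 20 genes were called, and 46 of the 49 named lost their calls.

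**Figure D4:**
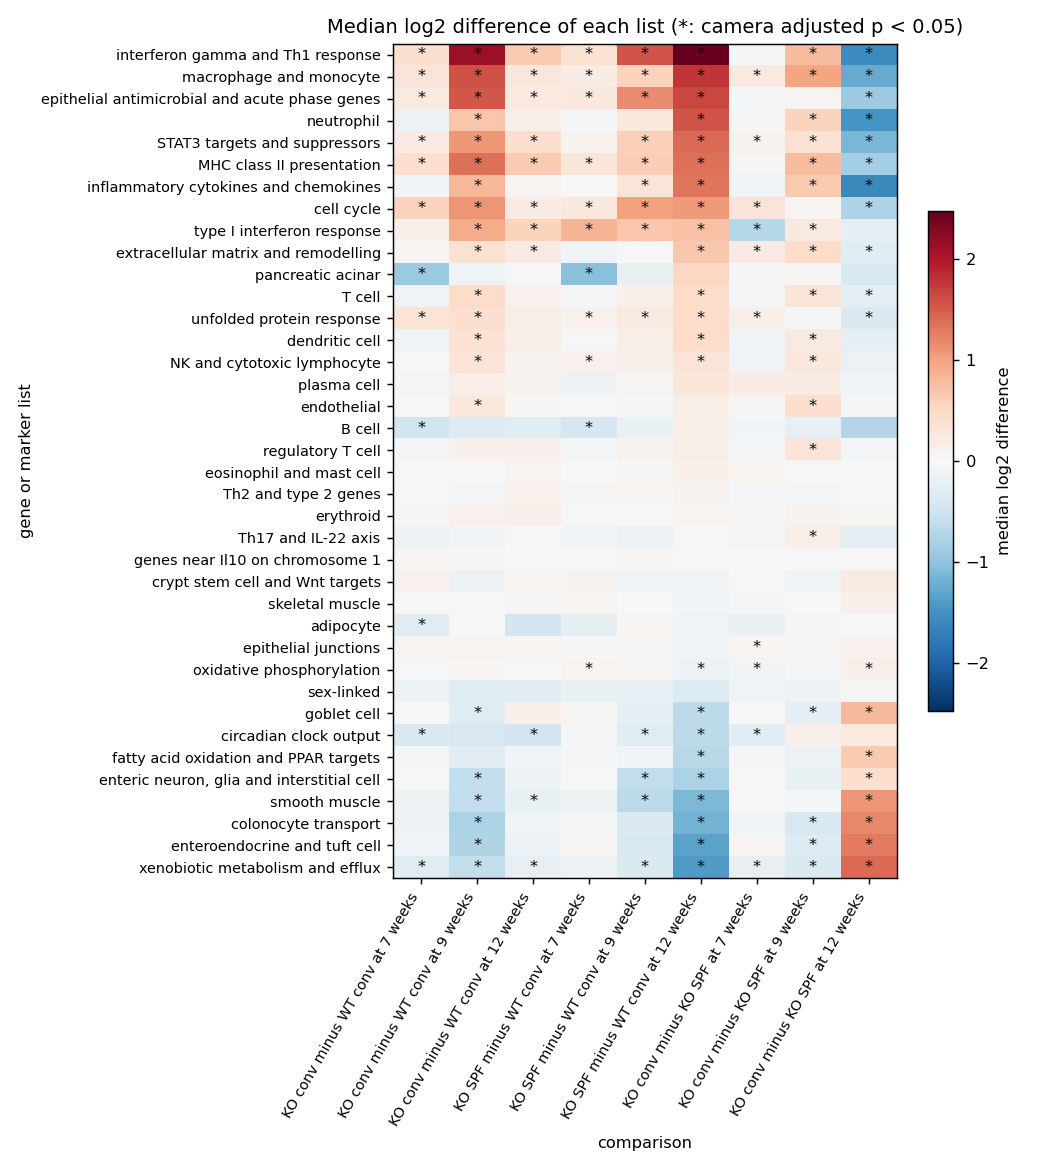
Median log2 difference of each gene or marker list (lines of the map) in each comparison of groups at 7, 9 and 12 weeks (columns), with an asterisk where camera called the list. The interferon gamma and Th1 list had a median of 0.77 between conventional and SPF knockouts at 9 weeks and -1.55 at 12 weeks.

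Averaged over the ages limma called 0 genes between the knockouts (1731 at an unadjusted p under 0.05), and 719 without SPF knockout 12-week replicate 2, 1 without conventional knockout 9-week replicate 3 and 1160 with array weights. Il10 was at -0.29 ± 0.17, adjusted p = 0.579. For smooth muscle, 0 of 16 genes passed limma's test (13 higher at an unadjusted p under 0.05, 12 higher adjusted within the list, median 0.34, camera adjusted p = 2.94e-12, or 0.658 with an estimated correlation).

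Changes with age were compared within each kind of mouse. In conventional knockouts limma called 0 genes between 7 and 12 weeks (1065 at an unadjusted p under 0.05), with Il10 at -0.05 ± 0.29, adjusted p = 0.996. In SPF knockouts 5071 genes changed (2509 higher and 2562 lower at 12 weeks). S100a8 (7.25 ± 1.12, adjusted p = 0.000304), Cxcl5 (6.15 ± 0.87), Lrg1 (4.83 ± 0.66), Cxcl9 (4.43 ± 0.69) and Il10 (1.66 ± 0.29) rose, and Dbp (-5.97 ± 0.67, adjusted p = 2.97e-05), Mptx1 (-5.51 ± 1.38), Cyp2c55 (-4.94 ± 0.96) and Myh11 (-1.47 ± 0.24) fell. For neutrophils, 13 of 16 genes rose (14 higher adjusted within the list, median 1.62, camera adjusted p = 1.13e-07, or 0.198 with an estimated correlation). For the clock, 4 of 17 genes rose and 10 fell (5 higher and 10 lower adjusted within the list, median -1.29, camera adjusted p = 0.000664, or 0.175 with an estimated correlation). The count was 394 with these 6 arrays alone, 3272 and 2524 without 12-week replicate 1 or 3, and Mptx1 lost its call without replicate 1. With the clock score as a covariate limma called 0 genes (1454 at an unadjusted p under 0.05).

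In wild types 22 genes changed between 7 and 12 weeks (5 higher, 17 lower), among them Col1a1 (-1.34 ± 0.25, adjusted p = 0.0305), named after its value was seen, and Il10 was at -0.05 ± 0.29, adjusted p = 0.962. For pancreatic acinar markers, 0 of 10 genes passed limma's test (4 lower at an unadjusted p under 0.05, 1 lower adjusted within the list, median -0.92, camera adjusted p = 0.00312, or 0.999 with an estimated correlation). Without wild-type 7-week replicate 1, the array with the high acinar mean, the median was -0.117 and the call was lost, as it was without 12-week replicate 1. The count was 2 and 1 without wild-type 7-week replicate 1 or 2, 497 and 0 without wild-type 12-week replicate 1 or 2 (1604 at an unadjusted p under 0.05 by limma in the latter), and 70 without SPF knockout 12-week replicate 2. Col1a1 lost its call without any 7-week wild-type array or without 12-week replicate 2 or 3.

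The difference of conventional knockouts from wild types was itself compared between 12 and 7 weeks, and limma called 0 genes (2088 at an unadjusted p under 0.05), with Il10 at 0.002 ± 0.41. Without wild-type 12-week replicate 1 the count was 40, and without wild-type 7-week replicate 1 or 3 it was 1 or 4. For type I interferon, 0 of 21 genes passed limma's test (5 higher at an unadjusted p under 0.05, 0 adjusted within the list, median 0.41, camera adjusted p = 0.0115, or 0.947 with an estimated correlation), a call lost without wild-type replicate 3 of 7 or 12 weeks.

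The difference between conventional and SPF knockouts changed from 7 to 12 weeks in 1701 genes (616 higher, 1085 lower). It fell for S100a8 (-7.51 ± 1.58, adjusted p = 0.012), Cxcl5 (-5.69 ± 1.23), Lrg1 (-4.31 ± 0.93) and Il10 (-1.71 ± 0.41), and rose for Dbp (6.71 ± 0.94, adjusted p = 0.00137), Cyp2c55 (5.28 ± 1.36) and Myh11 (1.37 ± 0.34). For xenobiotic metabolism, 21 of 34 genes rose (26 higher adjusted within the list, median 1.54, camera adjusted p = 7.17e-14, or 0.27 with an estimated correlation). For the cell cycle, 16 of 24 genes fell (21 lower adjusted within the list, median -1.06, camera adjusted p = 2.72e-14, or 0.27 with an estimated correlation). Every conventional and SPF knockout array at 7 or 12 weeks except conventional 7-week replicate 2 moved this count by more than 1.5 times: it was 508 and 267 without conventional 7-week replicate 1 or 3, 913, 261 and 557 without SPF 7-week replicate 1, 2 or 3, 1014, 358 and 624 without conventional 12-week replicate 1, 2 or 3, 327, 4521 and 177 without SPF 12-week replicate 1, 2 or 3, and 538 with the arrays of these groups alone. Cxcl5, Lrg1, Cyp2c55, Myh11 and Il10 lost their calls without SPF 12-week replicate 3, and the last 3 also without at least 3 other arrays. All 7 genes lost them with the clock score as a covariate, where limma called 0 genes (1135 at an unadjusted p under 0.05) and Dbp turned to -0.45.

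Chosen after the data were seen, the change of the same difference from 9 to 12 weeks was called in 3387 genes (1443 higher, 1944 lower). S100a8 (-11.66 ± 1.58, adjusted p = 0.000552) and Lrg1 (-6.46 ± 0.93) fell, and Cyp2c55 (5.73 ± 1.36) and Myh11 (1.48 ± 0.34) rose. For interferon gamma and Th1 genes, 1 of 29 genes rose and 25 fell (1 higher and 25 lower adjusted within the list, median -2.31, camera adjusted p = 2.25e-17, or 0.188 with an estimated correlation). The count was 1734 without conventional 9-week replicate 1, and 1562 and 1901 without SPF 9-week replicate 1 or 2. It was 1862, 5494 and 1571 without SPF 12-week replicate 1, 2 or 3. With only the arrays compared it was 26, and no named gene kept its call.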

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

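The change between 9 and 12 weeks, the clock score as a covariate and the tests of normalization and muscle wall as explanations, of the clock genes and of the genes apart were chosen only after the result was seen.

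A test of the change with age picked out the difference between conventional and SPF knockouts, since at 12 weeks the arrays labelled SPF carried the inflammatory genes: from 7 to 12 weeks it changed in 1701 genes (S100a8 -7.51, Cxcl5 -5.69, Lrg1 -4.31, Il10 -1.71, Cyp2c55 5.28, Dbp 6.71, Myh11 1.37), or 0 by limma with the clock score as a covariate (1135 at an unadjusted p under 0.05), and from 9 to 12 weeks in 3387 (S100a8 -11.66, Lrg1 -6.46, Cyp2c55 5.73, Myh11 1.48). Normalization stays open: a second pass moved the 12-week count of 4480 to 4554 at most, but the values were already normalized. Less muscle wall alone would raise epithelial markers, but these fell. SPF minus conventional medians were -1.29 for enteroendocrine and tuft cells (fry adjusted p = 0.00162), -1.19 for colonocyte transport and -0.80 for goblet cells. Less muscle (median -1.09) beside an epithelial loss stays open. Exchanged 12-week labels stay open: of 58 genes with a housing difference of 1 sign at 7 and 9 weeks (chance gives 22.7, and 199 had opposite signs), 29.3% kept the sign at 12 weeks, between the bounds set in advance for right and exchanged labels. A later onset of colitis in SPF housing would also need a decline in conventional knockouts. Their S100a8 averaged 10.26 ± 1.01 (SD, n = 3) at 9 weeks and 3.49 ± 0.07 at 12 weeks. Such a decline was not tested apart from the labels or the choice of replicates by colon damage.

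Clock genes separated the conventional knockouts from both other groups at 7 weeks. Tissue taken at another time of day could account for this, and within groups the deviations of the 7 lower and 4 higher clock genes ran against each other over 27 arrays (Pearson r = -0.671, permutation p = 0.0824, and Spearman rho = -0.355, permutation p = 0.184, the only relation across arrays tested), with r = -0.425 without the 2 arrays farthest from the median. That p misses the threshold and no collection times are given, so this stays open. Inflammation stays open too. The median difference of these 11 genes from wild types, picked and signed by 7-week calls, was 2.17 at 7 weeks. It was 0.56 (SD 0.79) at 9 weeks, where inflammatory genes differed more. In SPF knockouts it rose from -0.04 at 7 weeks to 1.81 at 12 weeks. Housing or age alone cannot account for the pattern, since the wild types shared both, while a joint effect of genotype and housing was not tested apart.

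In 56 genes, 43 higher and 13 lower, every knockout array lay apart from every wild-type array, against 0 genes in each of 100 relabellings. Carriage of chromosome 1 sequence beside the knocked-out Il10 is a candidate explanation for part of them: 14.5% of 55 (8 genes, Il10 left out) lie on chromosome 1 against 5.83% of other genes (Fisher exact p = 0.0141). Inflammation is argued against for those 8, whose median absolute difference of SPF knockouts from wild types at 12 weeks was 1.02 times that at 7 weeks (1.09 and 1.11), while that of the other 47 genes went from 0.40 to 1.62. A sequence variant under the probes stays open, since 42.9% (3 of 7) of other probe sets of these genes were called the same way.

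Probe sets without a single gene symbol, outside the gene tests, carried calls in 1011 of 10092 between conventional knockouts and wild types at 9 weeks, in 874 between the knockouts at 12 weeks and in 1650 between SPF knockouts and wild types at 12 weeks.

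Other splits of the same arrays were counted for every comparison. Of 100 splits, only the real split reached its count for the average of conventional knockouts against wild types (3344 genes, highest other split 2636). The same held for SPF knockouts (6410, highest other 2928) and for the change from 7 to 12 weeks between knockouts (1701, highest other 1560). This argues against chance without excluding it. Chance stays open for the change from 9 to 12 weeks (3387), where 5 of 100 splits gave as many and the highest other gave 5733. For the average difference between knockouts and the change from 7 to 12 weeks of conventional knockouts against wild types the splits show nothing about chance, since limma called 0 genes (1731 and 2088 at an unadjusted p under 0.05) and each of 100 splits reaches that count by definition (highest other 1651 and 50 at an adjusted p). Splits that call many more genes than the real one could reflect a structure of the samples, which was not tested. With 3 arrays against 3 the 10 splits are too few for a share under 0.05. The real count and the highest other were 92 and 1 at 7 weeks, 4375 and 0 at 9 weeks and 82 and 0 at 12 weeks for conventional knockouts against wild types, 10 and 0, 2155 and 0, and 6329 and 1499 for SPF knockouts against wild types, and 49 and 1, 0 and 16, and 4480 and 1234 between the knockouts. For 12 against 7 weeks they were 0 and 0 in conventional knockouts, 5071 and 927 in SPF knockouts and 22 and 1 in wild types.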

How the results depend on the processing

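The tests with the clock score as a covariate and the change between 9 and 12 weeks were chosen only after the result was seen. Of 252 camera calls of lists, 251 lost their call with an estimated inter-gene correlation, which left 1, while none turned direction with the replicate block (12 lost), quantile normalization again (7), centred arrays (3), the lowest 40% of genes left out (47), all probe sets (9), the mean of probe sets (9), an intensity trend (1), array weights (21) or only the arrays compared (8). Of 307 named gene results none turned under these settings, and calls were lost in 14 with the block, 88 with only the arrays compared and 10 or fewer under each of the others, with 263 of 263 kept where the lowest 40% of genes were left out. Leaving out 1 array ended 202 of 6804 list results and 283 of 8289 gene results and turned 1, the matrix and remodelling list in the average difference between knockouts by camera's direction (median 0.016 without SPF knockout 12-week replicate 2, range 0.016 to 0.148). The arrays give no signal over background beyond the deposited values, so leaving out the lowest 40% of genes stands in for it.

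With array weights, counts were 763, 7659 and 5749 for conventional knockouts against wild types at 7 and 9 weeks and on average, 253, 3681, 6997 and 1160 between the knockouts at 7, 9 and 12 weeks and on average, 139 and 6223 for SPF knockouts against wild types at 7 and 9 weeks, 5 for 12 against 7 weeks in conventional knockouts, 19 and 5685 for the changes from 7 to 12 weeks against wild types and SPF knockouts, and 7903 from 9 to 12 weeks. The lowest weight was 0.193, for SPF knockout 12-week replicate 2, and the cause was not tested. Among all non-control probe sets, more features were tested, and counts in the same order of comparisons were 7718, 199 and 6372 (9 and 12 weeks, average), 74, 2, 7513 and 7, then 74, 3548, 11893 and 12806 for SPF knockouts against wild types, 8879 for 12 against 7 weeks in SPF knockouts and 5390 from 9 to 12 weeks. With a minimum absolute log2 difference of 1, a stricter criterion by construction, counts were 43, 868, 25 and 145, then 24 and 938 between the knockouts at 7 and 12 weeks, 303, 1446 and 348 for SPF knockouts against wild types at 9 and 12 weeks and on average, 1237 and 4 for age in SPF knockouts and wild types, 822 from 7 to 12 weeks and 1478 from 9 to 12 weeks.

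With only the arrays compared setting the spread, counts were 34 for conventional and 1321 for SPF knockouts against wild types at 12 weeks. Between the knockouts they rose from 49 to 81 at 7 weeks and fell from 4480 to 20 at 12 weeks. For age they were 394 and 0 (1637 unadjusted by limma) in SPF knockouts and wild types. For the changes from 7 to 12 and 9 to 12 weeks they were 538 and 26. With the replicate block counts were 30 for conventional knockouts against wild types at 12 weeks, 2827 and 0 (1349 unadjusted by limma) for age in SPF knockouts and wild types, and 896 from 7 to 12 weeks. Replicate numbers do not pair the arrays: deviations of same-numbered arrays had a median r of 0.006 over 27 pairs across genes, which are not independent, and 4 pairs had r over 0.1, so the block is no better model. The mean of probe sets gave 1 gene for the average difference between knockouts, quantile normalization 100 and the lowest 40% left out 61 for age in wild types. The cause was not tested.

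With the clock score as a covariate counts were 0, 8 and 15 for conventional knockouts against wild types (7 and 12 weeks, average), 0 between the knockouts at 7 weeks, 281, 189 and 1107 for SPF knockouts against wild types (9 and 12 weeks, average), and 0 for age in SPF knockouts and for the change from 7 to 12 weeks between knockouts (limma; 1167, 1032, 1454 and 1135 genes unadjusted in the 4 cases of 0). The score is built from clock genes and separates groups, so by its construction it removes group differences, and it ended 63 list calls and 116 gene calls. The named genes that turned were the clock genes Dbp to 0.90, Nr1d2 to 0.023, Tef to 0.54 and Arntl to -0.17 and the macrophage marker Cd14 to -0.033 for conventional knockouts against wild types at 7 weeks, Dbp to 0.26 on average, and between the knockouts at 7 weeks Dbp to 0.88, Nr1d2 to 0.056, Tef to 0.63, Hlf to 0.81 and Arntl to -0.085, with Dbp at 0.036 for SPF knockouts against wild types at 9 weeks and -0.45 for the change from 7 to 12 weeks. List medians that turned were, against wild types at 7 weeks, MHC class II -0.026, xenobiotic 0.45, unfolded protein -0.074, cell cycle -0.18 and clock 0.065, at 12 weeks xenobiotic 0.049 and cell cycle 0.008, and on average neutrophil -0.004 and enteroendocrine 0.039. Between the knockouts at 7 weeks they were STAT3 -0.11, matrix -0.043, xenobiotic 0.60, junctions -0.075, unfolded protein -0.12, cell cycle -0.38, clock 0.19 and macrophage -0.31. For age they were unfolded protein -0.061 in SPF knockouts and cell cycle -0.03 in wild types, and for the changes from 7 to 12 weeks unfolded protein 0.012 and cell cycle 0.13 (against wild types), and between the knockouts unfolded protein 0.06, clock -0.066, and MHC class II -0.27 and fatty acid oxidation 0.093, where camera's direction turned and the median kept its sign.

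Leaving out 1 array, counts ranged from 30 to 156, 2119 to 5058, 11 to 834 and 2349 to 4145 for conventional knockouts against wild types (7, 9 and 12 weeks, average), 18 to 64, 0 to 185, 1357 to 6246 and 0 to 719 between the knockouts, and 7 to 38, 283 to 3023, 4533 to 7339 and 5333 to 7342 for SPF knockouts against wild types. For age they ranged from 2524 to 6503 in SPF knockouts and 0 to 497 in wild types, and for the changes with age from 0 to 40, 177 to 4521 and 1562 to 5494. Camera calls ranged from 233 to 268. A left-out array leaves 2 in its group, which are assumed to vary like the other groups.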

Other observations

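All tests in this part were chosen only after the result was seen.

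In SPF knockouts Dbp averaged 10.22 ± 0.09 (SD, n = 3 arrays) at 7, 4.57 ± 0.59 at 9 and 4.25 ± 0.39 at 12 weeks. Arntl averaged 6.26, 8.07 and 7.60. In wild types Dbp averaged 10.18, 6.75 and 8.33 (SD 2.12 at 12 weeks, replicate 3 at 5.93). Several genes with no overlap between knockout and wild-type arrays sit on chromosome 1 with Il10: besides Wdfy1, Stk25, D2hgdh and Gal3st2 these include the aminopeptidase gene Rnpep, higher by 0.55 ± 0.10 in conventional and 0.66 ± 0.10 in SPF knockouts on average, and the metalloreductase gene Steap3, at -0.54 and -0.65.

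The changes of conventional knockouts at 9 weeks and of SPF knockouts at 12 weeks, both against wild types of their age, share no arrays. As a hypothesis, both may reflect 1 shared inflammatory program reached at different ages: 99.9% of the 3334 genes called in both had the same sign (2008 higher, 1323 lower), where independent calls would give 469 and 298. The 3 exceptions included Abca12, a lipid transporter gene, at 0.89 and -1.14. This does not separate exchanged 12-week labels from a difference in timing, which would also need a decline in conventional knockouts by 12 weeks.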
